A study of Saccharomyces cerevisiae with 10 samples.

How the data were processed

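RNA from 10 cultures of Saccharomyces cerevisiae was labelled with biotin and hybridised to 1 Affymetrix yeast array each, per the labels' protocols. The deposited values are 1 linear intensity per probe set and array. The software used for probe set summary, background correction and scaling is not given in the sources used here. From the values, the authors scaled each array's intensities: the mean over all probe sets, leaving out 2% at each end, was 500.2 on each of the 10 arrays. Such scaling to one target per array makes arrays comparable only if the mean signal of the strains is alike. The highest intensity on any array was 9612.

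The table holds 10928 probe sets. The platform annotation pairs 7244 with 1 gene, 1 with several and 3683 with none. Of the latter 213 are controls. Gene symbols were updated by gene identifier to the R64 RefSeq gene table, which matched 5498 probe sets of S. cerevisiae. The other 1746 named probe sets are for Schizosaccharomyces pombe, an organism not studied here, and they served as background. Genes with several probe sets (47) were represented by the one with the highest mean over all arrays, which left 5449 genes. No coordinates are printed because the array files name no genome build, and chromosomes and neighbours at chromosome ends come from the gene table.

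Intensities were floored at 0 and taken as log2(intensity + 16). Fold changes are on that scale and understate changes of dim genes. Array medians over the tested genes differed by 1.11 times at most, under the limit of 1.2 fixed in advance, so no further scaling was applied. Medians over all probe sets, unnamed ones included, differed more. They were 60.6 to 64.0 on the wild-type arrays and 89.7 to 104 on the deletion arrays. The background limit of an array was the percentile 95 of its S. pombe probe sets. A gene at or under the limit on every array of a group has only a bound there. It is given as "at least N-fold", from the mean log2 intensity of the bright group and, for the dim group, the mean of the higher of the limit and the measured value on each array, without the added 16. MF(ALPHA)1 lay near the limit in the deletion arrays, under it on some of them and not on all.

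Groups came from the sample titles: wild type (n = 3), first restreaking (n = 4) and 12th restreaking (n = 3). The design text calls the samples of a group independent clones. Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per group over all 10 arrays, eBayes with an intensity trend, two-sided, Benjamini-Hochberg adjustment over the genes, threshold 0.05). All 3 groups share 1 estimate of the spread because each has 3 or 4 arrays. A change with an adjusted p under the threshold is called higher or lower. 44 gene lists were fixed before the data were examined. The 41 with at least 5 measured members were tested with limma's camera with a preset inter-gene correlation of 0.01 and again with an estimated one, adjusted over lists within a comparison. Camera's p measures whether a list's members shift relative to all other genes. ADE5,7 and DUR1,2 were not matched by name and are missing from their lists. The Y-prime helicase, mitochondrially encoded and Ty lists had no measured member. The 10 outermost genes at each chromosome end formed another set. For each array and chromosome, the median of log2 intensity minus the wild-type mean was tested with limma over 16 chromosomes.

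Genes were named by a rule fixed before the data were examined. It takes SUA5, and for each comparison the 8 largest rises and 8 largest falls among genes past the threshold whose arrays do not overlap between the groups. It also takes up to 4 members with the smallest adjusted p from each list that passed and from the lists of mating type a, mating type alpha, auxotrophic markers, telomerase and telomere proteins, and KEOPS and t6A. Of the lists that passed, at most 2 members each are named, a number set after the values were seen to keep the text short. The 7 genes called in opposite directions were named after their values were seen. A probe set with several genes was not named.

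The tests were tried on simulated data in which 200 of 5449 genes changed. For the first restreaking against wild type, 95.5% of genes changed by 0.5 on the log2 scale and all of those changed by 2 were recovered, with 6 false calls. For the 12th against the first restreaking the recovery at 0.5 was 97.0%, with 7 false calls. The simulations held no clone-to-clone structure beyond the estimated spread and no difference in scaling between arrays. They also changed far fewer genes than were called against wild type. Their recovery and false calls therefore do not carry over to comparisons in which most genes differ. In the first restreaking, replicates 1 and 2, and replicates 3 and 4, resembled each other more than they did the other pair. The SD of their log2 difference was 0.136 and 0.121, and between the pairs it was 0.217 to 0.236. The fits hold no term for these pairs, so the p-values treat the 4 clones as independent.

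Alternatives fixed in advance were quantile normalization, equal array medians, a filter on dim genes, all probe sets, eBayes without trend or robust, array weights, the replicate number as a block, pseudocounts of 1 and 64, a 2-fold threshold, only the 2 groups compared, leaving out mating type and marker lists, other set tests (fry), other chromosome summaries, 5 or 20 outermost genes, and leaving out each array. Fits with replicates 1 and 2 or replicates 3 and 4 of the first restreaking alone were added after seeing LYS2 and MET17, and so were equal medians for the lists and an estimated correlation for chromosome ends. Figures were drawn with matplotlib 3.10.9, and tables were prepared with Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6.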

Results

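Gene expression was measured in budding yeast (Saccharomyces cerevisiae) lacking SUA5 and in wild-type cells, on 10 Affymetrix yeast arrays with 1 culture each. Sua5 is an enzyme of the pathway that makes the modified base threonylcarbamoyladenosine (t6A) in tRNAs, and it is also known for a role at telomeres. The deletion strains came from spores of a heterozygous BY4743 diploid and had mating type a, per the labels. They were sampled after the first restreaking on rich medium (4 clones, labelled as 35 generations after sporulation) and after the 12th restreaking (3 clones, labelled as 300 generations). The wild type was BY4742, a haploid laboratory strain of mating type alpha (3 clones). The design text calls the clones of each group independent, but those of the first restreaking resembled each other in pairs. All cultures were harvested in mid-log growth in rich liquid medium. The 5449 genes tested had a median intensity between 602 and 666 on each array. Between 97.7% and 99.1% of them lay above that array's background limit of 10.8 to 17.5. The number of arrays limits the precision of every value below.

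SUA5 (YGL169W) checked the labels. Its intensity was 506, 522 and 532 on the 3 wild-type arrays. It was 0.342, 5.1, 3.17 and 1.2 on the 4 arrays of the first restreaking and 5.22, 4.93 and 2.18 on the 3 arrays of the 12th, all under the background limit. SUA5 was therefore at least 40.5-fold lower at the first restreaking (adjusted p = 1.66e-13) and at least 45.4-fold lower at the 12th (adjusted p = 5.32e-13).

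Genes that mark mating type separated the deletion strains from the wild type. All 7 measured a-specific genes were higher at the first restreaking, with STE2, the alpha-factor receptor, 24.5-fold higher (1948 ± 172, SD, n = 4, against 64.1 ± 6.39, n = 3). The a-factor gene MFA2 was 28.4-fold higher, the a-factor transporter gene STE6 8.58-fold and the agglutinin subunit gene AGA2 10.3-fold. All 6 measured alpha-specific genes were lower. The alpha-factor gene MF(ALPHA)1 fell from 5343 ± 55.8 (SD, n = 3) to 13.0 ± 2.31 (n = 4), near the background limit. MF(ALPHA)2 was lower (4680 ± 81.2, SD, n = 3, to 22.2 ± 3.48, n = 4), and STE3, the a-factor receptor, was 17.5-fold lower. HMRA1 was at least 38.6-fold higher and HMLALPHA1 at least 75.5-fold lower. The last pair of probe sets also match the identical copies at the mating type locus. As lists, the a-specific genes rose (adjusted p = 8.73e-05 by camera; adjusted p = 0.163 with an estimated correlation) and the alpha-specific genes fell (adjusted p = 1.51e-05; adjusted p = 0.135 with an estimated correlation). Every comparison with the wild type therefore also compared mating type a with mating type alpha.

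2 auxotrophic marker genes divided the clones of the first restreaking. LYS2, needed to make lysine, read 2953 and 2890 in replicates 3 and 4, and 15.6 and 9.34 in replicates 1 and 2. MET17 (also called MET15), needed to make methionine, read 4898 and 4662 in replicates 3 and 4, and 15.3 or less in replicates 1 and 2. On the arrays of the 12th restreaking LYS2 read 53.7, 29.3 and 10.8 and MET17 read 96.9, 30.6 and 8.09. The wild type had MET17 at 4250 ± 114 (SD, n = 3) and LYS2 at 13.1 ± 3.69. With this spread, LYS2 passed the threshold at the first restreaking against wild type (adjusted p = 0.0451) and MET17 did not (adjusted p = 0.0544). The call of LYS2 was lost without either of replicates 3 and 4 (adjusted p = 0.126 and 0.134), without any 1 of the wild-type arrays (adjusted p = 0.0973, 0.0817 and 0.0969) and without any 1 of the 12th restreaking (adjusted p = 0.0542, 0.0563 and 0.0517). MET17 passed without replicate 3 or 4 (adjusted p = 0.00691 and 0.0089). With replicates 1 and 2 alone, a choice made after seeing the data, the log2 change of LYS2 was -0.033. The same pairs appeared across all genes: deviations from the group mean correlated at 0.399 between replicates 1 and 2 and at 0.487 between replicates 3 and 4, and between -0.759 and -0.693 across the pairs, although genes are not independent replicates. HIS3 was 2.53-fold higher than in the wild type (adjusted p = 4.16e-12). LEU2 (adjusted p = 0.0865) did not pass, except without replicate 2 of the first restreaking or wild-type replicate 1 (adjusted p = 0.0244 and 0.0332), and URA3 stayed under the background limit on all 10 arrays.

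**Figure D1:**
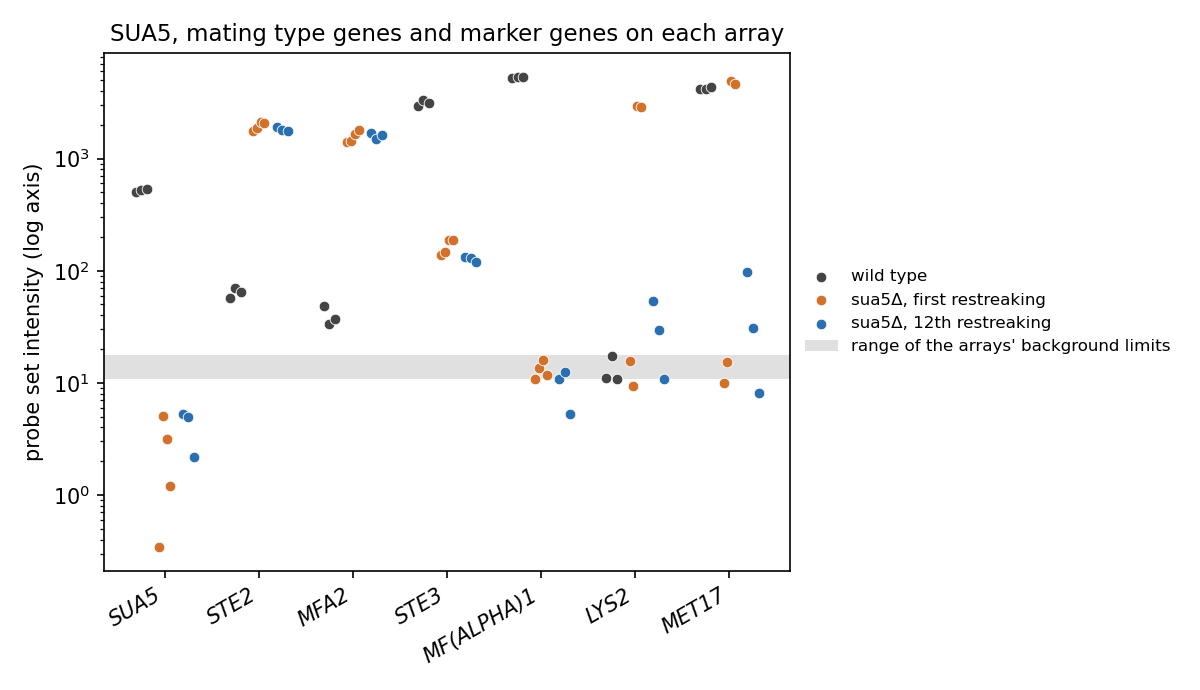
Probe set intensity (log axis) of SUA5, 4 mating type genes and 2 marker genes, with 1 point per array for wild type (n = 3), first restreaking (n = 4) and 12th restreaking (n = 3). The grey band spans the arrays' background limits of 10.8 to 17.5, and LYS2 and MET17 are bright in only 2 of the 7 deletion arrays, replicates 3 and 4 of the first restreaking.

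The comparison of the first restreaking with the wild type asked how expression differs soon after SUA5 is lost. By camera with a preset correlation, the general stress list of Msn2 and Msn4 and the list of gluconeogenesis, the glyoxylate cycle and fat oxidation rose, and the ribosomal protein, cell cycle and phosphate regulon lists fell. Of these lists only the phosphate regulon also passed with an estimated correlation, and the heat shock, oxidative stress, TCA cycle and respiratory chain lists did not pass (adjusted p = 0.546, 0.816, 0.0983 and 0.106). After quantile normalization the TCA cycle and respiratory chain lists did pass (each adjusted p = 0.00626). In limma's test, 4306 of 5449 genes changed, 2262 higher and 2044 lower. Of these, 708 changed at least 2-fold, 559 of them higher. Besides the mating genes, the largest rises were in SPG4, a gene needed for survival in stationary phase (4640 ± 705, SD, n = 4, against 63.9 ± 21.9, n = 3, 59.5-fold), and in YNL194C (41.8-fold). SNO1, of pyridoxine synthesis, rose 37.8-fold, YNL034W 30.8-fold, its close relative YNL018C 27.8-fold and the protein kinase gene RCK1 27.4-fold. The largest falls outside the mating genes and SUA5 were in PHO84, the high-affinity phosphate transporter (66.0-fold), PTR2, the di- and tripeptide transporter (31.5-fold), and SPL2, a phosphate-regulated inhibitor of low-affinity phosphate uptake (21.3-fold). YNL034W and YNL018C are close paralogs, so their values are uncertain as measures of each gene alone. In the wild type SNO1 and YNL018C lay near the background limit, and under it on replicate 2, so their folds against wild type are imprecise.

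Of the general stress genes controlled by Msn2 and Msn4, 58 of 63 rose and 3 fell (median 2.95-fold, adjusted p = 1.87e-13 by camera; adjusted p = 0.215 with an estimated correlation). DCS2 rose 6.28-fold and TSL1, a subunit of the trehalose synthase complex, 3.8-fold. In gluconeogenesis, the glyoxylate cycle and fat oxidation, 28 of 31 genes rose and 1 fell (median 3.1-fold, adjusted p = 1.24e-07; adjusted p = 0.255 with an estimated correlation). Malate dehydrogenase MDH2 rose 2.86-fold and the peroxisomal citrate synthase CIT2 4-fold. CIT2 is also a target of the retrograde response, of whose 17 genes 14 rose and 1 fell (adjusted p = 0.00175; adjusted p = 0.135 with an estimated correlation). CRC1, the mitochondrial carnitine carrier, rose 12.9-fold, an imprecise value since the wild type read 23.3 ± 7.07 (SD, n = 3), near the background limit. Of 55 amino acid biosynthesis genes controlled by Gcn4, 44 rose and 5 fell (median 1.39-fold, adjusted p = 5.89e-07; adjusted p = 0.135 with an estimated correlation). Argininosuccinate synthetase ARG1 rose from 290 ± 29.9 (SD, n = 3) to 4661 ± 203 (n = 4), 15.3-fold, and the cyclin gene PCL5, a Gcn4 target, 4.83-fold.

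Genes under nitrogen catabolite repression also rose, 27 of 35 with 4 falling (adjusted p = 0.000129; adjusted p = 0.078 with an estimated correlation). DAL2, of allantoin breakdown, rose 6.58-fold and UGA3, an activator of GABA use, 3.34-fold. Of 18 thiamine and pyridoxine genes, 14 rose and 2 fell (adjusted p = 0.000978; adjusted p = 0.078 with an estimated correlation), with SNZ1 up 12.0-fold. Of 11 galactose and maltose genes, 9 rose and 1 fell (adjusted p = 0.00271; adjusted p = 0.123 with an estimated correlation), with the maltose permease gene MAL31 up 5.46-fold. In the COS family, 7 of 9 genes rose (adjusted p = 0.0168; adjusted p = 0.33 with an estimated correlation), COS8 by 4.17-fold. Among the seripauperins and related cell wall genes, 13 of 19 rose and 3 fell (adjusted p = 0.0162; adjusted p = 0.255 with an estimated correlation). DAN4 rose 3.93-fold and TIR1 fell 8.56-fold. COS and seripauperin genes are near-identical families whose probe sets cannot always tell members apart. Meiosis and sporulation genes rose in 24 of 39 cases and fell in 3 (adjusted p = 0.00356 by camera, but 0.185 after quantile normalization and 0.206 with an estimated correlation). This rise does not show diploid cells: HMLALPHA1, whose probe set also matches the mating type locus, lay under the background limit on every deletion array. REC8, the meiotic cohesin gene, read 95.8 ± 9.85 (SD, n = 4) against 14.3 ± 1.97 (n = 3).

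3 lists passed with less margin. Of 27 sulfur and methionine genes 19 rose and 6 fell (adjusted p = 0.0343), of 37 iron regulon genes 23 rose and 8 fell (adjusted p = 0.0377), and of 20 hexose transporter genes 12 rose and 2 fell (adjusted p = 0.0424). Without replicate 2 of the first restreaking each of the 3 had an adjusted p of 0.0506, and with replicates 3 and 4 alone 0.0728, 0.0635 and 0.0626. Hexose transporters also missed the threshold without wild-type replicate 1 (adjusted p = 0.0535) or 3 (adjusted p = 0.0619). With an estimated correlation their adjusted p was 0.562, 0.206 and 0.215. MET16 rose 2.6-fold and the S-adenosylmethionine synthetase gene SAM2 fell 2.21-fold. The scaffold gene for iron-sulfur clusters ISU1 rose 3-fold and the glucose transporter gene HXT5 9.36-fold.

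Of 128 cytosolic ribosomal protein genes 126 fell and none rose (median 1.27-fold lower, adjusted p = 1.32e-17; adjusted p = 0.178 with an estimated correlation). RPS28B fell 3.31-fold and RPS17B 1.88-fold, from 6489 ± 269 (SD, n = 3) to 3453 ± 183 (n = 4). In ribosome biogenesis 66 of 93 genes fell and 8 rose (adjusted p = 2.76e-07; adjusted p = 0.3 with an estimated correlation), including BFR2 (2.61-fold). Of 27 G1/S cell cycle genes 24 fell and 1 rose (median 2.05-fold lower, adjusted p = 1.24e-07; adjusted p = 0.163 with an estimated correlation). The cohesin gene MCD1 fell 4.25-fold. All 9 histone genes fell (adjusted p = 8.29e-05; adjusted p = 0.152 with an estimated correlation), HHO1 by 2.45-fold. Of 32 G2/M and M/G1 genes 22 fell and 2 rose (adjusted p = 0.000325; adjusted p = 0.206 with an estimated correlation), the polo kinase gene CDC5 by 1.61-fold. Of 26 haploid and pheromone response genes 14 fell and 5 rose (adjusted p = 0.00857; adjusted p = 0.267 with an estimated correlation). FAR1, which arrests the cycle on pheromone, fell 4.69-fold and FUS1 4.01-fold, between strains of opposite mating type.

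The phosphate regulon fell in 17 of 20 genes and rose in 2 (median 2.5-fold lower, adjusted p = 3.89e-06), and it alone of the 41 lists passed with an estimated correlation as well (adjusted p = 0.0467). VTC3, of the polyphosphate polymerase complex, fell 7.52-fold. Of 28 ergosterol genes 23 fell and 1 rose (adjusted p = 8.56e-06; adjusted p = 0.078 with an estimated correlation), ERG5 by 2.92-fold and ERG6 by 2.42-fold. 4 more lists fell by camera but lost the call after quantile normalization. Cytosolic aminoacyl-tRNA synthetases fell in 16 of 18 cases (adjusted p = 0.000325, 0.113 after quantile normalization; adjusted p = 0.311 with an estimated correlation). Proteasome genes fell in 25 of 37 cases and rose in 3 (adjusted p = 0.000349, 0.0542 after quantile normalization; adjusted p = 0.135 with an estimated correlation). Unfolded protein response genes fell in 21 of 35 cases and rose in 8 (adjusted p = 0.00984, 0.0566 after quantile normalization; adjusted p = 0.116 with an estimated correlation). Purine synthesis genes fell in 10 of 17 cases and rose in 4 (adjusted p = 0.0162, 0.251 after quantile normalization; adjusted p = 0.215 with an estimated correlation). ADE17 fell 3.97-fold and ADE2 2.35-fold.

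The lists of telomere genes and of the pathway of Sua5 did not pass by camera. Of 26 telomerase and telomere protein genes 11 rose and 12 fell (median log2 change -0.052, adjusted p = 0.765). TEN1, which caps telomeres, rose 2.3-fold and the telomerase subunit gene EST3 1.59-fold, while the silencing gene SIR3 fell 1.76-fold and NAM7 1.36-fold. Of the 7 KEOPS and t6A genes, KAE1 rose 1.37-fold. SUA5, QRI7 and GON7 fell, and the list as a whole gave an adjusted p of 0.614 by camera. By fry, which does not set a list against the other genes, the same list fell (adjusted p = 4.85e-06, and 9.21e-06 at the 12th restreaking). The list includes SUA5, the deleted gene, whose log2 change was -4.87 at the first restreaking, while the list's median was -0.06. The fry result therefore does not show a fall of the other members. The call of QRI7 (1.17-fold lower) was lost without replicate 4 of the first restreaking or wild-type replicate 2 or 3 (adjusted p = 0.0637, 0.0777 and 0.0909). That of GON7 (1.19-fold lower) was lost without replicate 2 of the first restreaking or wild-type replicate 1 or 3 (adjusted p = 0.0796, 0.131 and 0.0552). The DNA damage response (12 of 27 higher, 12 lower, adjusted p = 0.765) and homologous recombination lists (13 of 23 higher, 10 lower, adjusted p = 0.901) gave no call. The last had a median log2 change of 0.26 while its test pointed down.

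The 10 outermost genes at each chromosome end, 224 in all, rose as a set on the values as deposited. At the first restreaking 153 rose and 36 fell (153 and 38 adjusted over the list alone), with a median log2 change of 0.61 (p = 8.37e-07 by camera, p = 0.00811 with an estimated correlation). Without multigene families and shared probe sets 108 of the remaining 165 genes rose and 31 fell (108 and 33 adjusted over the list alone), with a median log2 change of 0.55. After quantile normalization these medians were smaller, 0.32 for all 224 genes and 0.27 for the 165.

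Over the 41 lists tested at the first restreaking, 27 passed. Counts of members adjusted over the list alone equalled those over all genes in 35 lists and differed by at most 1 gene in the other 6. Setting the array medians equal moved the median of all genes against wild type down by 0.109 on the log2 scale (first restreaking) and 0.111 (12th), and quantile normalization moved it by 0.103 and 0.101. The share of the changed genes that were higher, 52.5% at the first restreaking, was then 44.2% and 42.9%. The median of no list that passed changed sign under that scaling or under quantile normalization.

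**Figure D2:**
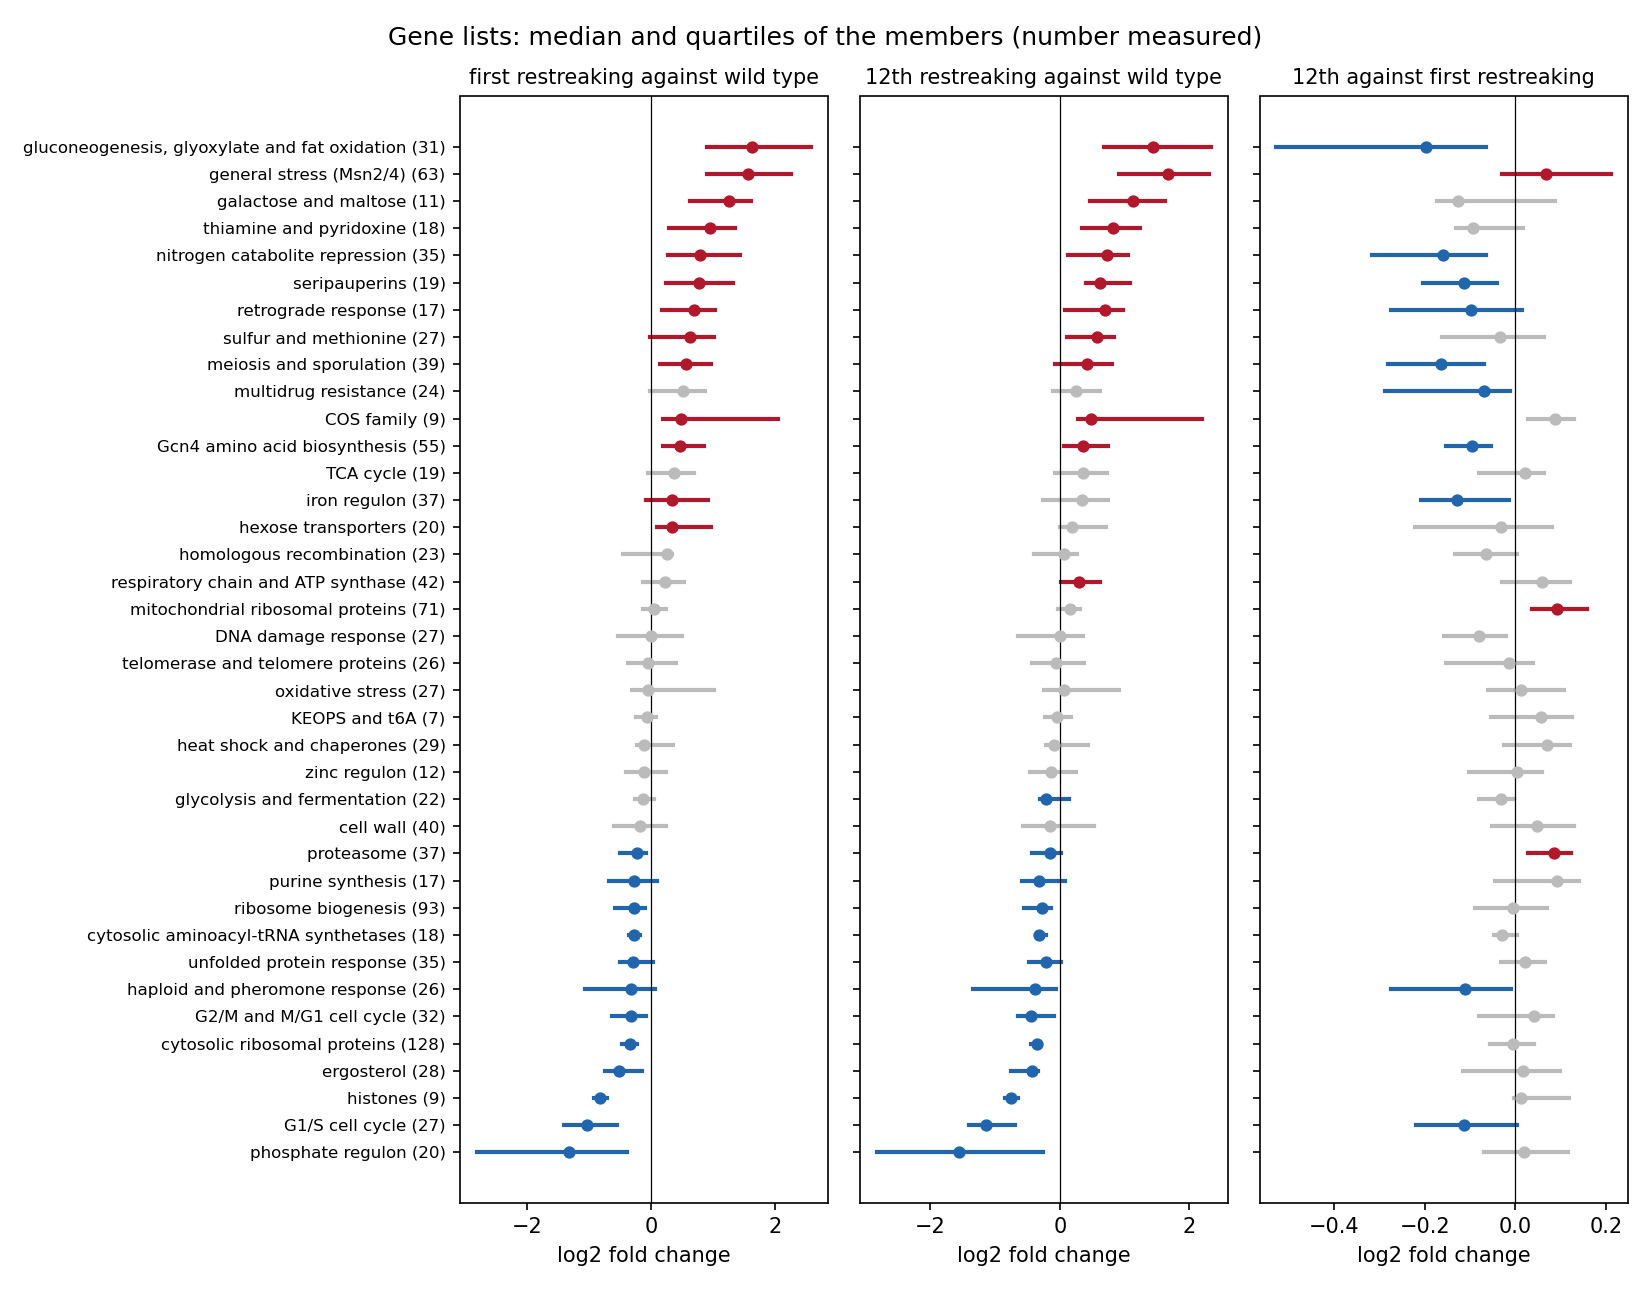
Median (point) and quartiles (line) of the log2 fold change of the members of each gene list, with the number of genes measured in parentheses; the mating type and marker lists are left out. Red and blue lists rose and fell by camera with a preset correlation (adjusted p under 0.05), grey lists did not pass, and the panel for 12th against first restreaking has its own scale.

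The comparison of the 12th restreaking with the wild type asked what the expression state is after long propagation. By camera with a preset correlation the same lists of general stress and of gluconeogenesis rose, and those of ribosomal proteins, the cell cycle and the phosphate regulon fell, but none of them passed with an estimated correlation. The heat shock, oxidative stress and TCA cycle lists did not pass (adjusted p = 0.824, 0.662 and 0.131). The heat shock list pointed down here, but up and past the threshold after quantile normalization (adjusted p = 0.0251) and by fry (adjusted p = 0.00964). In all, 4239 of 5449 genes changed, 2231 higher and 2008 lower, and 688 changed at least 2-fold. Most changed genes were instead lower after quantile normalization (1789 higher, 2292 lower) and with equal array medians (1879 higher, 2384 lower). SPG4 (57.1-fold), YNL194C (46.7-fold), SNO1 (37.8-fold) and MFA2 (29.4-fold) were again among the largest rises, and so was PHM7, a member of the general stress list (24.1-fold). MET17, dim in all 3 clones, was 84.9-fold lower (adjusted p = 0.00328), and PHO84 was 51.0-fold lower. General stress genes rose in 58 of 63 cases and fell in 4 (adjusted p = 6.62e-14; adjusted p = 0.255 with an estimated correlation), with FMP45 up 14.2-fold. Cytosolic ribosomal proteins fell in 126 of 128 cases (adjusted p = 1.92e-18; adjusted p = 0.206 with an estimated correlation). G1/S genes fell in 25 of 27 cases (adjusted p = 5.1e-09; adjusted p = 0.176 with an estimated correlation), POL12 by 3.34-fold. The phosphate regulon fell in 15 of 20 cases and rose in 3 (adjusted p = 7.48e-06; adjusted p = 0.0542 with an estimated correlation).

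Of the 41 lists 27 passed at the 12th restreaking, 25 of them also past at the first and in the same direction. With an estimated correlation none did, their adjusted p running from 0.0542 to 0.542. Hexose transporters (adjusted p = 0.0859) and the iron regulon (adjusted p = 0.167) did not pass, although hexose transporters did after quantile normalization (adjusted p = 0.0418), as did the TCA cycle (adjusted p = 0.0113). After quantile normalization the calls of purine synthesis (adjusted p = 0.239), aminoacyl-tRNA synthetase, unfolded protein response and seripauperin genes (each adjusted p = 0.0848), and of proteasome and meiosis genes (each adjusted p = 0.3) were lost, the last also without wild-type replicate 2 (adjusted p = 0.0572). Counts adjusted over the list alone were equal in 40 lists and differed by 1 gene in the other. Respiratory chain and ATP synthase genes passed here, 25 of 42 higher and 7 lower (adjusted p = 0.0317, 0.0522 with equal array medians; adjusted p = 0.509 with an estimated correlation). SDH2 rose 2.69-fold, whereas the cytochrome c gene CYC1 fell 4.66-fold. Glycolysis and fermentation genes fell in 15 of 22 cases and rose in 5 (adjusted p = 0.0456; adjusted p = 0.542 with an estimated correlation), but with quantile normalization the test pointed up (adjusted p = 0.666). That call was also lost without replicate 1 or 2 of the 12th restreaking or wild-type replicate 2 (adjusted p = 0.0539, 0.0562 and 0.0725), with equal array medians (adjusted p = 0.0522), with the replicate number as a block (adjusted p = 0.0684) and with replicates 1 and 2 of the first restreaking alone (adjusted p = 0.0533). Telomerase and telomere protein genes again went both ways, with 10 of 26 higher and 12 lower (adjusted p = 0.581), STN1 1.94-fold higher and SIR2 1.78-fold lower. Chromosome end genes rose in 142 of 224 cases and fell in 39, also when adjusted over the list alone. Their median log2 change was 0.47, or 0.22 after quantile normalization. The set test was run on the values as deposited only (p = 1.35e-05 by camera, p = 0.0145 with an estimated correlation).

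Both restreakings were compared with the same 3 wild-type arrays. 3884 genes changed in the same direction in both, 2052 higher and 1832 lower, and 7 changed in opposite directions. Simulated unchanged groups against those wild-type arrays shared 1 gene at most in 100 draws. Independent lists of these sizes would share 926 higher and 753 lower genes. Across genes the 2 sets of fold changes correlated at 0.976 (0.534 in the simulation), with a covariance of 0.624 against a simulated 0.0037. Genes are not independent replicates, and the 3 wild-type arrays were too few to give each comparison its own controls.

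The comparison of the 12th with the first restreaking asked what changed during propagation itself. The changes were small: 866 of 5449 genes passed, 372 higher and 494 lower, and only 7 changed at least 2-fold. ARO9 and ARO10, of aromatic amino acid breakdown, rose 2.4-fold (adjusted p = 0.000106) and 1.63-fold (adjusted p = 0.00101). AQR1, an exporter of amino acids, rose 1.97-fold, FMP45 1.57-fold, the peptide transporter gene PTR2 1.48-fold and the mitochondrial ribosomal protein gene RSM19 1.47-fold. GDH3, a glutamate dehydrogenase, fell 2.96-fold, from 1108 ± 433 (SD, n = 4) to 343 ± 26.7 (n = 3). LYS20, homocitrate synthase of lysine synthesis, fell 2.52-fold, from 2187 ± 561 to 836 ± 6.6. At the first restreaking it read 1771 and 1645 in replicates 1 and 2, where LYS2 was dim as at the 12th. In replicates 3 and 4, where LYS2 was bright, it read 2762 and 2571, so part of this fall follows the clone pairs. CIT3 and PDH1, both of propionate use, fell 2.72-fold and 1.88-fold. The carnitine acetyltransferase genes YAT1 and YAT2 fell 2.24-fold and 1.84-fold, and the acyl-CoA oxidase gene POX1 2.16-fold. YDL241W and YOL014W (1.59-fold and 1.48-fold higher) and PRM2 (2.67-fold lower) completed the largest changes.

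The gene lists that fell between the restreakings included several that stood above the wild type at the first. Gcn4 amino acid biosynthesis fell in 13 of 55 genes (18 adjusted over the list alone) and rose in none (median 1.07-fold lower, adjusted p = 2.76e-08; adjusted p = 0.151 with an estimated correlation), with MET13 1.33-fold lower. Nitrogen catabolite repression genes fell in 13 of 35 cases and rose in none (14 and 1 adjusted over the list alone, adjusted p = 4.72e-06), the ammonium permease gene MEP2 by 1.43-fold. This list also passed with an estimated correlation (adjusted p = 0.0494). Gluconeogenesis, glyoxylate and fat oxidation genes fell in 12 of 31 cases and rose in 1 (15 and 1 adjusted over the list alone, adjusted p = 4.72e-06, but 0.0561 by fry; adjusted p = 0.465 with an estimated correlation). Iron regulon genes fell in 11 of 37 cases (15 adjusted over the list alone, adjusted p = 1.98e-05; adjusted p = 0.0974 with an estimated correlation). FET3, of high-affinity iron uptake, fell 1.35-fold and the siderophore transporter gene SIT1 1.39-fold. G1/S genes fell in 7 of 27 cases (9 adjusted over the list alone, adjusted p = 0.00447, but 0.0623 by fry; adjusted p = 0.498 with an estimated correlation), POL2 by 1.33-fold. Retrograde response genes fell in 5 of 17 cases (6 adjusted over the list alone, adjusted p = 0.0113; adjusted p = 0.329 with an estimated correlation), CRC1 by 1.65-fold. Multidrug resistance genes fell in 7 of 24 cases and rose in 2 (9 and 3 adjusted over the list alone, adjusted p = 0.00929; adjusted p = 0.133 with an estimated correlation), PDR10 by 1.3-fold.

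Mitochondrial ribosomal protein genes rose in 8 of 71 cases and fell in none (7 adjusted over the list alone, median 1.07-fold higher, adjusted p = 8.12e-06; adjusted p = 0.396 with an estimated correlation). Proteasome genes rose in 7 of 37 cases (10 adjusted over the list alone, adjusted p = 1.98e-05; adjusted p = 0.133 with an estimated correlation), RPN6 by 1.15-fold. General stress genes rose in 9 of 63 cases and fell in 3 (13 and 3 adjusted over the list alone, adjusted p = 0.0186; adjusted p = 0.825 with an estimated correlation). FMP45 rose and SIP18 fell 1.76-fold. With replicates 1 and 2 of the first restreaking alone, this list pointed down (adjusted p = 0.45). It also missed the threshold without replicate 3 or 4 of the first restreaking (adjusted p = 0.304 and 0.155) or replicate 2 of the 12th (adjusted p = 0.0605), with the replicate number as a block (adjusted p = 0.149) and by fry (adjusted p = 0.506). 2 lists of mating genes fell. Haploid and pheromone response genes fell in 6 of 26 cases and rose in 1 (8 and 2 adjusted over the list alone, adjusted p = 0.00929; adjusted p = 0.449 with an estimated correlation), the transcription factor gene STE12 by 1.34-fold. Alpha-specific genes, some of them dim in these a cells, fell in 1 of 6 cases (5 adjusted over the list alone, adjusted p = 0.0116; adjusted p = 0.449 with an estimated correlation). Both lost the call with replicates 1 and 2 of the first restreaking alone (adjusted p = 0.114 and 0.184), and the alpha-specific genes also after quantile normalization (adjusted p = 0.0901). Meiosis and sporulation genes fell in 6 of 39 cases, also adjusted over the list alone (adjusted p = 0.00274, 0.325 after quantile normalization; adjusted p = 0.329 with an estimated correlation), SPS4 by 1.57-fold. Seripauperins fell in 3 of 19 cases, also adjusted over the list alone (adjusted p = 0.0333; adjusted p = 0.45 with an estimated correlation). They missed the threshold without replicate 3 or 4 of the first restreaking or replicate 1 of the 12th (adjusted p = 0.0868, 0.0606 and 0.0678), after quantile normalization (adjusted p = 0.123), with the replicate number as a block (adjusted p = 0.0655), by fry (adjusted p = 0.0587) and with replicates 1 and 2 alone (adjusted p = 0.248).

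Of the telomerase and telomere protein genes, 1 rose and 3 fell out of 26 between the restreakings (1 and 5 adjusted over the list alone, adjusted p = 0.391 for the list). CDC13, which binds the telomeric overhang, fell 1.43-fold (225 ± 15.8, SD, n = 4, to 152 ± 6.19, n = 3, adjusted p = 0.0057), and YKU80, of the Ku complex, 1.28-fold (adjusted p = 0.00584). The chromosome end genes fell, with 49 of 224 lower and 11 higher (58 and 13 adjusted over the list alone). Their median log2 change was -0.086, or -0.043 after quantile normalization. The set test was again run on the values as deposited only (p = 0.000498 by camera, p = 0.0363 with an estimated correlation). In limma's test 0 of 7 KEOPS and t6A genes, 0 of 7 a-specific genes and 0 of 5 marker genes passed between the restreakings (1, 0 and 0 at an unadjusted p under 0.05), with LYS2 at an adjusted p of 0.214 and MET17 at 0.237.

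The count for this comparison depended on single arrays and on the clones of the first restreaking. It was 414 with the replicate number as a block and 1310 with array weights. It was 544, 375 and 267 without replicates 1, 2 and 3 of the 12th restreaking. With replicates 1 and 2 of the first restreaking alone it was 773, and with replicates 3 and 4 alone 611. 292 genes were called in the same direction with each pair, 92 higher and 200 lower, and 4 in opposite directions. Calls of some genes were lost without 1 array of the 12th restreaking. Among them were PRM2 (adjusted p = 0.089, 0.102 and 0.1 without replicates 1, 2 and 3) and STE3, the alpha-specific gene called (adjusted p = 0.059, 0.0893 and 0.141). Without replicates 2 and 3, YDL241W (adjusted p = 0.082 and 0.105) and YOL014W (adjusted p = 0.0797 and 0.0746) lost theirs. So did the telomere genes SIR3 (adjusted p = 0.0743 and 0.112) and RIF1 (adjusted p = 0.15 each). SIR3, RIF1 and STE3 also lost their calls without single arrays of the first restreaking. Leaving out 1 array of the first restreaking ended the call of PRM2 (adjusted p = 0.0739 and 0.0786 without replicates 3 and 4), YDL241W (adjusted p = 0.0579 without replicate 2) and YOL014W (adjusted p = 0.0505 without replicate 2). Robust eBayes also ended the calls of PRM2, YDL241W and YOL014W (adjusted p = 0.121, 0.0629 and 0.0576).

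**Figure D3:**
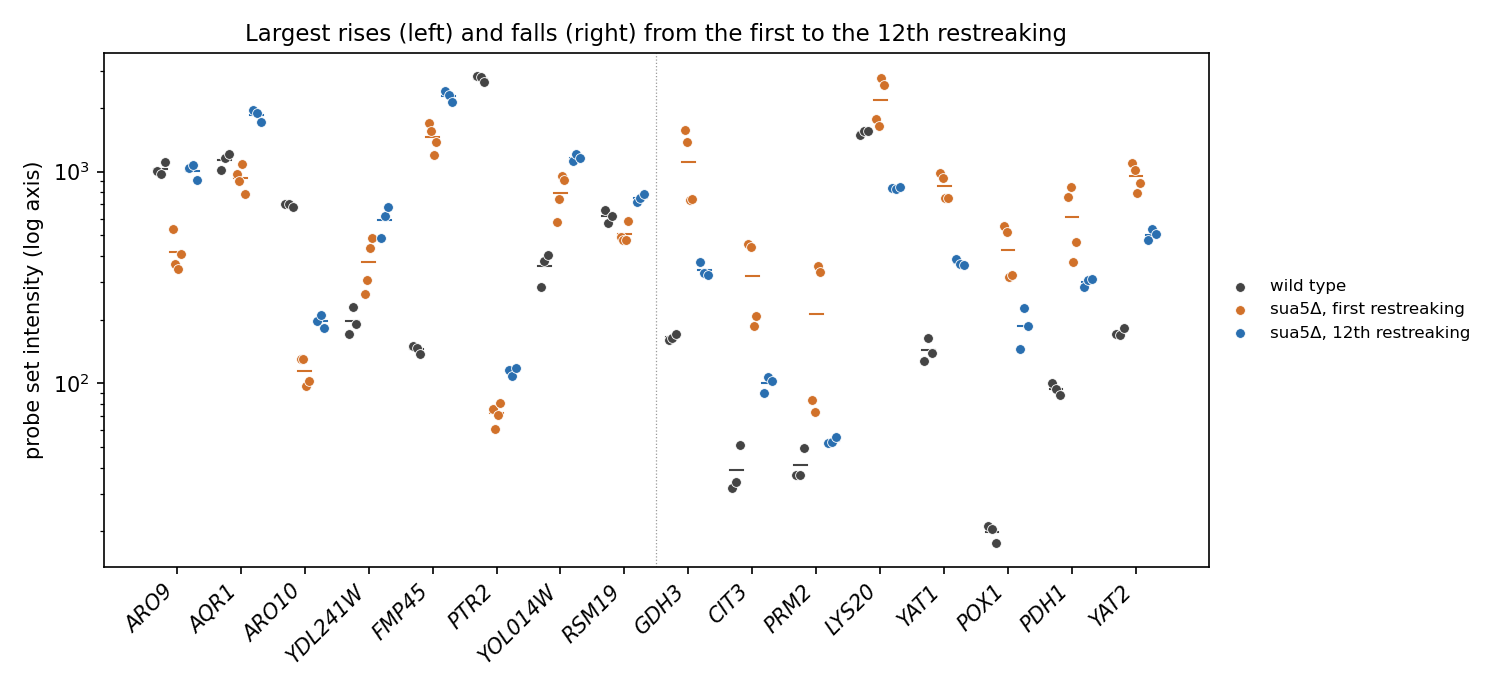
Probe set intensity (log axis) of the 8 genes with the largest rise and the 8 with the largest fall from the first to the 12th restreaking, with 1 point per array and a line at each group's mean, beside the wild type. GDH3, CIT3 and PRM2 are spread widely among the 4 clones of the first restreaking, while every array of the 12th lies below them.

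Chromosome medians gave no sign of a shift the size of a gained or lost chromosome. Over all 7 deletion arrays and 16 chromosomes the median farthest from the wild-type mean was 0.16 on the log2 scale, on chromosome IX in replicate 3 of the first restreaking. No array passed the limit of 0.3 set before the data were examined. Small shifts against the wild type passed limma's test on 11 of 16 chromosomes at each restreaking, the largest on chromosome III (0.13 at the first and 0.11 at the 12th). Equal array medians alone moved the median of all genes against wild type down by 0.109 at the first restreaking and 0.111 at the 12th. Chromosomes were not tested under another scaling, so which of them shifted against the wild type, and in which direction, is not settled. Between the restreakings 0 of 16 passed in limma's test (2 at an unadjusted p under 0.05), but 8 passed with means in place of medians, and 8 when the dimmest genes were left out.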

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

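The tests of the scaling, the mating type and marker genes, the strain background, the chromosomes and the 25S rRNA probe sets were chosen only after the results were seen, and so was the fit with replicates 1 and 2 of the first restreaking alone.

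Most genes differed between the deletion strains and the wild type: 4306 at the first restreaking, where 1 of 35 splits of the arrays gave as many and the highest other split gave 2653. This share counts against chance only if the clones are independent. Those of the first restreaking resembled each other in pairs, so the splits do not exclude chance. At the 12th (4239 genes, highest other split 0) the 10 splits are too few for a share under 0.05. The tables argue against the authors' scaling as the whole cause, since at least 66.0% of the genes tested were called in the deposited direction under both other scalings, although this majority bound replaced a bound on the calls kept that the 83.5% kept under quantile normalization had left undecided. The mating type and marker lists held 0.79% of the calls, which decides nothing, since lists this small could not hold many and effects of mating type on other genes were not tested. Loss of SUA5, mating type and other differences between BY4742 and the spores cannot be told apart, because 0 arrays of SUA5 spores from the cross were analysed here.

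The 12th restreaking differed from the first in 866 genes by limma's test of the difference, and 1 of 35 splits gave as many (highest other split 3). This share counts against chance only if the 4 clones of the first restreaking are independent. They resembled each other in pairs, so the splits do not exclude chance. The LYS2 and MET17 alleles of the clones are argued against as the whole cause. With replicates 1 and 2 of the first restreaking alone, where both genes are dim as at the 12th, 773 genes were called. Of the 866 genes, 63.7% were called in the same direction with that pair and 53.1% with replicates 3 and 4 alone. These shares are no separate evidence, since the 866 were chosen with the same arrays. A gained or lost chromosome is argued against by the farthest chromosome median of 0.16 on the log2 scale, although the farthest chromosome mean was 0.29. Movement back toward the wild type stays open: of 175 genes that changed at least 2-fold at the first restreaking and again by the 12th, 120 (68.6%) moved toward the wild type, between the bounds set in advance, but both comparisons share the first-restreaking arrays, and of all 708 genes changed at least 2-fold 57.6% did, against 52.2% (highest 55.8%) in 100 simulations without a change. Differences between the clones picked at each restreaking, apart from propagation, stay open and were not tested.

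The probe set for the 5′ end of 25S ribosomal RNA, a control outside the comparisons, read 650 ± 166 (SD, n = 7) in the deletion arrays and 4811 ± 2048 (n = 3) in the wild type. Breakdown of the RNA or shorter cDNA stays open. Of 4 ratios of 3′ to 5′ signal, 0 were higher and 1, that of SPT15, was lower in every deletion array than in every wild-type array. These ratios come from other transcripts (ACT1, TDH1, WBP1 and SPT15), so they do not measure the state of the 25S rRNA. Less 25S rRNA in general stays open: the wild type exceeded the deletion strains 7.40-fold at the 5′ probe set, 1.14-fold at the middle and 1.07-fold at the 3′ probe set, but the middle one read close to the highest value of the wild-type arrays, and 0 of the 38 genes at least as bright in the wild type as the 3′ one fell 1.5-fold, so these values do not show that a fall would register at that level. No biological explanation was tested.

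Among the 4 arrays of the first restreaking, GLN4 in replicate 1 (2493), HTA2 in replicate 3 (2823) and RSM19 in replicate 4 (586) lay far from the other 3 by Dixon's criterion. These were 3 of 150 such groups, and chance gives about 1 in 20. In 7 genes (PRP16, LYS20, RSM19, MDM38, AQR1, REX2 and LYS21) the 2 restreakings were called in opposite directions against the wild type. AQR1 read 1129 in the wild type, 937 at the first and 1848 at the 12th restreaking, and LYS20 read 1536, 2187 and 836. At the first restreaking LYS20 was highest in the clones with bright LYS2 (2762 and 2571 in replicates 3 and 4, 1771 and 1645 in replicates 1 and 2). Of 47 reporter control probe sets, 1 read 7156 ± 450 (SD, n = 7) in the deletion arrays and 11.7 ± 3.98 (n = 3) in the wild type. Of 3470 probe sets without a gene name, 45 were at least 2-fold higher in every deletion array than in every wild-type array, and 4 were lower.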

How the results depend on the processing

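Fits with a pair of first-restreaking clones alone, equal array medians for lists and an estimated correlation for chromosome ends were chosen only after the data were seen. With a 2-fold threshold the counts were 708 (first restreaking against wild type), 688 (12th against wild type), 7 (12th against first) and 615 in both, since fewer genes can pass. Between the restreakings array weights gave 1310 genes. The replicate block gave 414, and 3922, 3935 and 3575 for the first, the 12th and both; deviations of equal-numbered arrays correlated at -0.271, 0.08 and -0.193 across genes, so the numbers gave no sign of pairing. Leaving out 1 array gave 4185 to 4307, 4030 to 4275 and 267 to 921 genes, 3767 to 3871 in both, and 25 to 28, 25 to 27 and 13 to 17 lists. With an estimated correlation 1, 0 and 1 lists passed. Heat shock genes at the 12th restreaking turned to up after quantile normalization (adjusted p = 0.0251) and by fry (adjusted p = 0.00964). Glycolysis did so after quantile normalization (adjusted p = 0.666). With replicates 1 and 2 alone, general stress genes between the restreakings turned down (adjusted p = 0.45) and LYS2 read -0.033 on the log2 scale. With chromosome means the farthest value was 0.29 and 8 chromosomes passed between the restreakings; without the dimmest genes these were -0.11 and 8. By fry general stress (adjusted p = 0.506), gluconeogenesis (adjusted p = 0.0561), G1/S (adjusted p = 0.0623) and seripauperin genes (adjusted p = 0.0587) lost their call between the restreakings. DNA damage (adjusted p = 0.00679), thiamine (adjusted p = 0.0119), homologous recombination (adjusted p = 0.0407) and purine genes (adjusted p = 0.0418) gained one, and fry called 35 (first against wild type), 39 (12th against wild type) and 14 lists (12th against first) in all. Except for the 2-fold threshold, the cause was not tested. Of 1862 values of named genes between the restreakings, 1743 kept direction and call. Genes at or under the background limit on every array of a group have only bounds, and folds of genes near the limits are imprecise.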

Other observations

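The values below were chosen only after the results were seen, and no explanation was tested for them. Lists that did not pass at the first restreaking against wild type included multidrug resistance (15 of 24 genes higher, 5 lower, adjusted p = 0.0617), the TCA cycle (12 of 19 higher, 5 lower, adjusted p = 0.0983) and the cell wall (12 of 40 higher, 22 lower, adjusted p = 0.106). After quantile normalization multidrug resistance (adjusted p = 0.0227), the TCA cycle and the respiratory chain (each adjusted p = 0.00626) passed. Heat shock and chaperone genes went both ways (10 of 29 higher, 14 lower, 10 and 15 adjusted over the list alone, adjusted p = 0.546), and so did zinc regulon genes (3 of 12 higher, 6 lower, adjusted p = 0.392).

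Several genes that changed between the restreakings differed between the clones of the first. GDH3 read 1569 and 1383 in replicates 1 and 2, 733 and 744 in replicates 3 and 4, and 323 to 374 at the 12th. PRM2 read 83.5 and 73.5 in replicates 1 and 2, 359 and 336 in replicates 3 and 4, and 52.1 to 55.5 at the 12th. The middle control probe set of RIP1, of the respiratory chain, read 720 ± 57.1 (SD, n = 7) in the deletion arrays and 340 ± 31.5 (n = 3) in the wild type.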
